A study of Mus musculus with 16 samples.

How the data were processed

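RNA was sequenced from mouse cells sorted as podocytes, the epithelial cells that wrap the capillaries of the kidney filter. Per the labels, the mice carried an NPHS2-rtTA|tetO-Cre|tdTomato transgene set, in which doxycycline (625 mg/kg, for 21 days from an age of 3 weeks) starts a red fluorescent label in podocytes. Red cells were then sorted by flow cytometry. Young mice were 3 to 4 months old and aged mice 22 to 23 months old. The labels give 15 young females, 11 young males, 5 aged females and 3 aged males.

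The 16 libraries form 4 groups: 5 of aged females, 3 of aged males, 4 of young females and 4 of young males. Titles mark 6 libraries as pools of several animals, all of them young: the 4 young female libraries and young male replicates 3 and 4. The other 10 libraries are each treated as a single animal, so that a spread among aged libraries is a spread among mice, and a spread among young females is a spread among pools. The number of mice per pool is not given. Replicate numbers follow the order of the sample records and carry no pairing.

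The deposited table holds raw counts per gene (unit: counts), which are whole numbers from 0 with no normalization. The authors mapped the reads to mm10, which is GRCm38. The submitters' processing notes name Subread and HTSeq without roles or versions, and the strand setting is not stated. Libraries were made with a stranded mRNA kit and read as pairs. The table has 48440 gene entries, of which 19965 have no count in any library, and 48058 match an identifier in GENCODE M21. Of these, 96.28% carry the same symbol in the annotation, and 113 symbols stand on more than 1 entry. No column with counts was left out.

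Total counts per library ran from 8103388 to 19078201. Reads were amplified by PCR and carry no molecular identifiers, so intervals and floors cover counting error only.

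Counts were analysed in R 4.3.3. The main test was edgeR's (4.0.16) quasi-likelihood F-test, two-sided and robust, with TMM scaling and the filter of filterByExpr by group (minimum count 10), which kept 17686 genes and at least 99.864% of the counts of each library. The model had 1 mean per group over all 16 libraries and 1 dispersion per gene. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. CPM values are TMM-scaled, and log2 CPM has a prior count of 2.

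There were 6 comparisons: aged against young averaged over the sexes, in females, and in males, the difference between the male and the female age change, and males against females in young and in aged mice. The age comparisons in females and in males share no library, only the dispersion. The 2 sex comparisons share no library either.

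Gene lists (36) were written before the data were examined, as were the comparisons, the rule for named genes and the processing alternatives. They cover podocyte genes, signalling, immune, metabolic and stress genes, and markers of other kidney and blood cells, and some genes are in more than 1 list. Lists were tested with limma's (3.58.1) camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, for the 4 age comparisons, adjusted over the 36 lists within a comparison. The percent of counts in 10 marker lists was compared between ages by a two-sided exact permutation test on the log2 percent, adjusted over the 10 lists. The smallest p it can give is 0.000155 over all libraries, 0.00794 in females and 0.0286 in males. A list of 20 leukocyte genes outside the fixed lists was written later, before its members' values were seen.

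Named genes had an adjusted p under 0.05, an average log2 CPM of at least 2 and no overlap between the groups compared. The 12 with the largest rise and the 12 with the largest fall were taken for the averaged age comparison, and 5 each way for each sex's age change and for each sex comparison. For the difference in age change, the 5 largest each way with an adjusted p under 0.05 and that average were taken. Predicted genes without a name and immunoglobulin or T cell receptor segments with V, D, J or C in the symbol were skipped. The up to 4 members of each list with the smallest p in the averaged age comparison were added. Nphs1, Nphs2, Wt1, Synpo, Podxl, Cdkn1a, Cdkn2a, Pdcd1, Cd274, Xist and Ddx3y were always given. List members that moved against their list were named after their values were seen.

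Alternatives were DESeq2 (1.42.0), RLE size factors, upper quartile scaling, no filter, at least 50 counts in 3 libraries, limma voom with sample weights, only the groups compared, a term for pooled libraries, no pooled young males, the mean log2 CPM of proximal tubule markers as a covariate, each library left out in turn, additive age and sex, and age alone. For the percent of counts in markers, the total without mitochondrial genes and the mean log2 CPM of the members were tried. Alternatives chosen after seeing the data were total count scaling, leaving out all mitochondrially encoded genes, and leaving out the single-animal young males. The pool term can be estimated from the young males alone, since no other group holds both kinds of library.

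The main test was tested on simulated counts with the means and dispersions of these libraries, no group difference, and changes of known size added to some genes. Of 17686 genes 67 were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. In the real averaged age comparison 63% of the genes changed, so the rates below need not hold there. The dispersions were estimated by edgeR, which may favour it over DESeq2. In the averaged age comparison edgeR recovered 97% of the genes changed by 2 on the log2 scale, 55.2% at 1 and 29.9% at 0.5, with 3.97% false calls, against 100%, 73.1% and 46.3% with 18% false calls for DESeq2. For the difference in age change between the sexes edgeR recovered 68.2%, 16.4% and 1.49%, with 3.39% false calls.

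Of 184 named genes, 49 share exon sequence with another annotated gene and 38 of these with a gene on the other strand. Since the strand setting is unknown, counts of Crb2 (with Dennd1a), Psmb9 (with Tap1), Ndufs1 (with Eef1b2) and Nr1d1 (with Thra), whose partners on the other strand had more counts than they did, are less certain, as are those of immunoglobulin constant genes, hemoglobin genes and H2 genes, whose sequences resemble one another.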

Results

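Gene expression was measured by RNA sequencing in cells sorted for a podocyte label from young and aged mice of both sexes, and the series compares the ages. The 16 libraries comprised 5 of aged females, 3 of aged males, 4 of young females and 4 of young males. All aged libraries were from single mice, and 6 of the 8 young ones were pools. Total counts averaged 10960000 ± 1481000 (SD, n = 8) in aged and 14700000 ± 2748000 (SD, n = 8) in young libraries, and 19243 to 22312 genes had a count in a library. Gene positions are given on GRCm38.

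The main axis of variation among the libraries separated the ages. Pooling and cell type markers differed between the same groups, so this axis cannot be assigned to age alone. The leading principal component held 58.75% of the variance and separated every aged library (-106.2 to -53.41) from every young library (59.85 to 104.8). The next component held 7.487% and placed females above and males below 0.

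**Figure D1:**
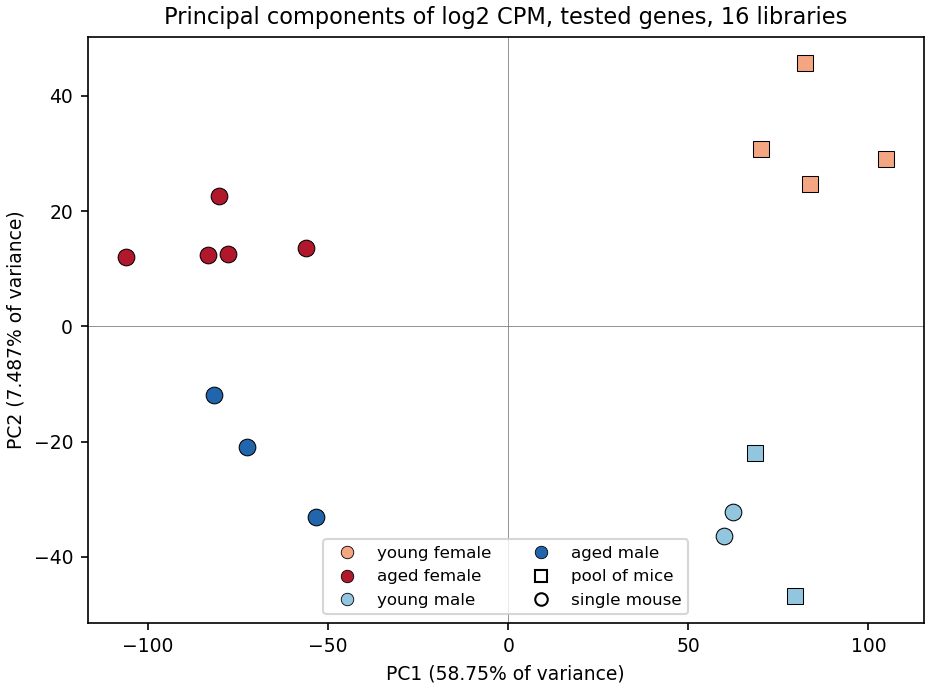
Principal components of log2 CPM for the 16 libraries, with component 1 (58.75% of the variance) on the x axis and component 2 (7.487%) on the y axis. Colours mark the 4 groups, squares pools and circles single mice, and the aged libraries lie between -106.2 and -53.41 on component 1.

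Cell type markers shifted between the ages as well. Markers of macrophages and dendritic cells took 0.712 ± 0.0726% of the counts (SD, n = 8) in aged and 0.126 ± 0.0373% (SD, n = 8) in young libraries. This was a 5.88-fold rise, with exact p = 0.000155, the smallest possible, and adjusted p = 0.000259. Markers of lymphocytes and plasma cells rose 24.3-fold, from 0.0244 ± 0.00776% to 0.650 ± 0.393% (SD, n = 8 each, exact p = 0.000155, adjusted p = 0.000259). The percent of counts in slit diaphragm and foot process genes was 2.38-fold lower, at 0.218 ± 0.0182% against 0.542 ± 0.168% (SD, n = 8 each, exact p = 0.000155, adjusted p = 0.000259). Podocyte transcription factor and differentiation genes were 2.81-fold lower by the same measure (exact p = 0.000155, adjusted p = 0.000259). A summed percent weighs the members with the most counts, and Nphs1, Nphs2 and Wt1 fell much further, as given below. These folds therefore do not measure the share of podocytes. Markers of other kidney cells were lower too: proximal tubule 2.18-fold, loop, distal and collecting duct 2.05-fold, endothelium 2.00-fold, mesangium and smooth muscle 1.87-fold and parietal epithelium 1.55-fold (adjusted p 0.000259 to 0.00622, exact permutation). Erythroid markers were 7.04-fold lower (exact p = 0.000155), and their percent was highest in young males 1 and 2 (0.126% and 0.21%).

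**Figure D2:**
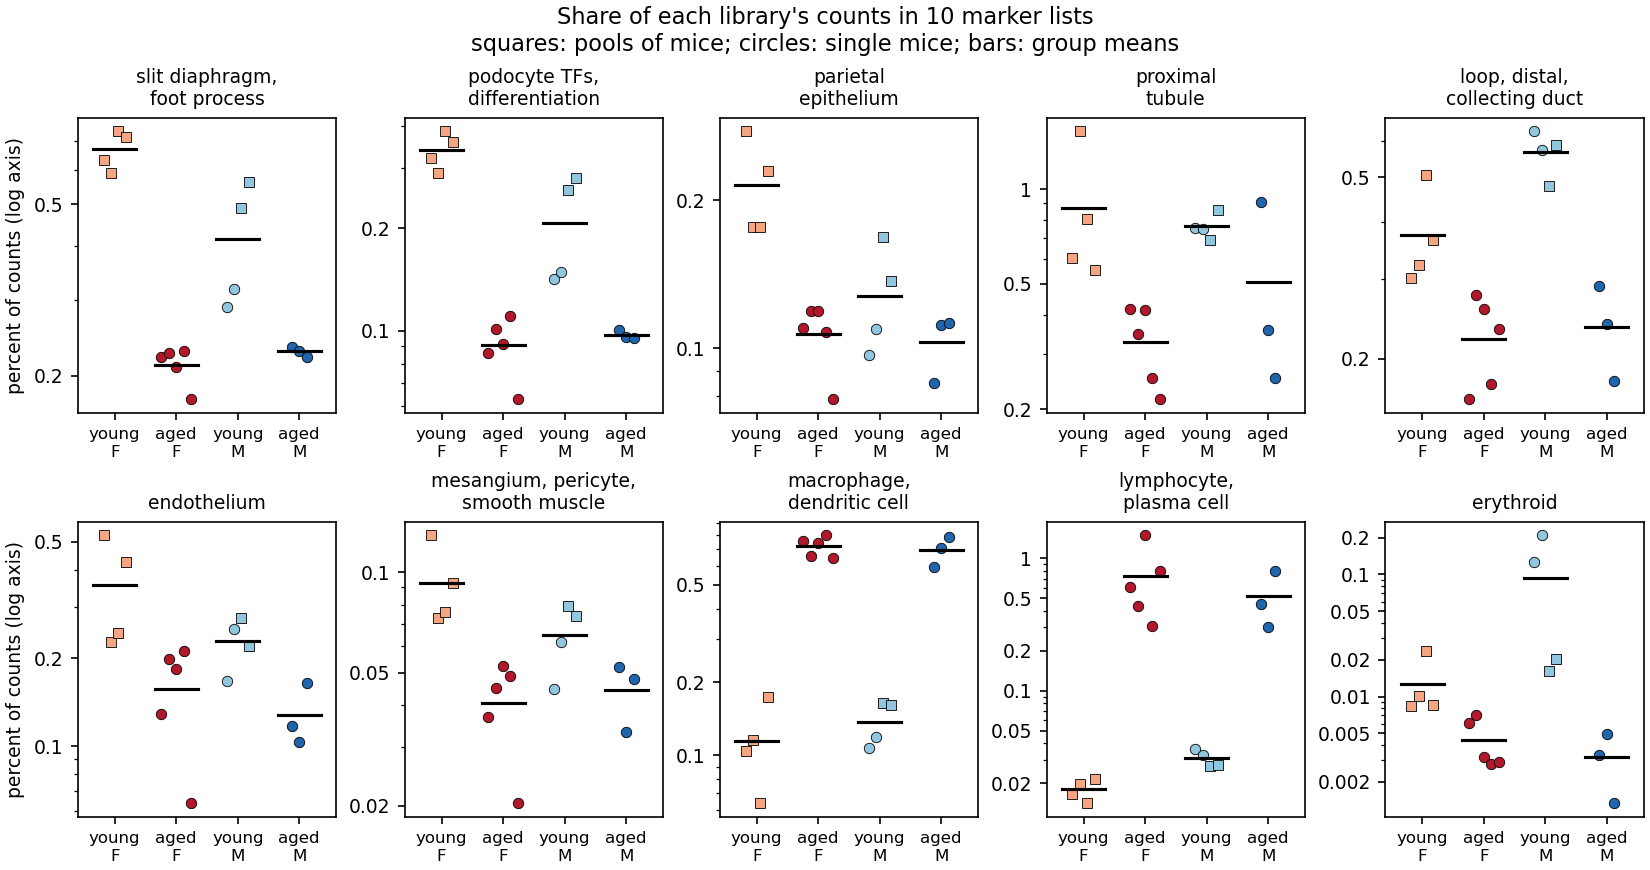
Percent of counts in 10 marker lists (log y axis) for each of the 16 libraries, grouped by age and sex. Macrophage and dendritic cell markers took 0.712% on average in aged and 0.126% in young libraries, and the podocyte, tubule, endothelial and erythroid lists were lower in aged libraries.

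Mitochondrial RNA also differed. Mitochondrial ribosomal RNA took 14.3 ± 2.84% of counts in aged and 26.9 ± 7.75% in young libraries (SD, n = 8 each, 1.84-fold lower, exact p = 0.000466, adjusted p = 0.000622). Messenger RNA of mitochondrial genes took 2.71 ± 0.696% and 5.96 ± 2.04% (SD, n = 8 each, 2.15-fold lower, exact p = 0.000466, adjusted p = 0.000622). Young males 1 and 2, the only single-animal young libraries, had the highest values, with ribosomal RNA at 38.8% and 35.9%. Immunoglobulin segments rose 38.9-fold, from 0.0252 ± 0.0134% to 1.08 ± 0.816% (SD, n = 8 each, exact p = 0.000155, adjusted p = 0.000622).

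What differs with age in the libraries of sorted cells, averaged over the sexes, was the main question. Since markers of other cells shifted as well, a change in a library need not be a change within podocytes. Transcripts that define podocytes fell in aged libraries, and transcripts of antibody genes, of leukocytes, of antigen presentation and of cell division rose. Nphs1 (nephrin, the core protein of the slit diaphragm) averaged 2.75 ± 2.45 CPM in aged and 129 ± 68.4 CPM in young libraries (SD, n = 8 each). Igha, the constant gene of immunoglobulin A, averaged 2035 ± 1361 CPM against 64.1 ± 50.5 CPM (SD, n = 8 each). In total 11142 of 17686 genes (63%) changed, 5566 up and 5576 down, and 2892 rose and 2901 fell by 2-fold or more.

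The largest falls by the rule for named genes included podocyte genes. Lmx1b, a transcription factor needed for podocyte development (chromosome 2, 33560965 to 33640511, minus strand), fell by 5.47 on the log2 scale (SE 0.50, adjusted p = 1e-07). Nphs1 (ENSMUSG00000006649.17, chromosome 7, 30458315 to 30487223, plus strand) fell by 5.43 (SE 0.46, adjusted p = 4.96e-08). Nphs2 (podocin, ENSMUSG00000026602.9, chromosome 1, 156310727 to 156328035, plus strand), which anchors nephrin, fell by 5.39 (SE 0.44, adjusted p = 2.79e-08), to 7.88 ± 4.83 CPM from 362 ± 206 CPM (SD, n = 8 each). Wt1 (ENSMUSG00000016458.13, chromosome 2, 105126529 to 105173616, plus strand), the master transcription factor of podocytes, fell by 4.64 (SE 0.31, adjusted p = 2.04e-09), to 2.05 ± 1.69 CPM from 50.5 ± 19.7 CPM (SD, n = 8 each). The other large falls were in Tdrd5 (-5.32), Nell2 (-5.13), Ddn, a postsynaptic and podocyte protein (-5.01), Myom2 (-4.94), Sema3e (-4.84), Clic3 (-4.75), the cell cycle inhibitor Cdkn1c (-4.74) and the polarity gene Crb2 (-4.69). All 8 aged libraries lay below all 8 young ones in each of these genes, as the rule that picked them required. The ages did not overlap in 4982 of all 17686 genes tested. Podxl (podocalyxin, the charged coat of foot processes) fell by 2.88 (SE 0.25, adjusted p = 5.18e-08) and Synpo (synaptopodin, an actin organizer of foot processes) by 2.72 (SE 0.20, adjusted p = 6.51e-09).

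Of 30 tested slit diaphragm and foot process genes, 24 fell and 1 rose, with a median log2 change of -1.93 (adjusted p = 5.41e-13, and adjusted p = 0.139 with an estimated correlation). They included the scaffold Magi2 (-3.64), the polarity gene Pard3b (-2.58), the phospholipase Plce1 (-2.83) and the Rac inhibitor Arhgap24 (-2.08). Arhgdia, which holds Rho GTPases inactive, rose (0.54). Of 28 podocyte transcription factor and differentiation genes 25 fell, among them Robo2 (-3.78), Foxc1 (-2.53) and Srgap1 (-3.65), at a median of -2.42 (adjusted p = 1.69e-14, and adjusted p = 0.126 with an estimated correlation). The riser was Mafb (1.19), a transcription factor of podocytes and of macrophages. Of 24 genes of the glomerular basement membrane and its receptors, 18 fell and 3 rose (median -1.13, adjusted p = 2e-07, and adjusted p = 0.196 with an estimated correlation). The collagen IV chain Col4a3 fell by 2.57 (adjusted p = 1.33e-09), Col4a5 by 2.21, laminin Lamb1 by 2.18 and kindlin-2 (Fermt2) by 1.94, and the adhesion genes Tln1 (1.01), Pxn (0.26) and Ilk (0.25) rose. The VEGF, angiopoietin and endothelial ligand list had 12 falls and 2 rises in 18 genes (median -1.11, adjusted p = 0.000252, and adjusted p = 0.196 with an estimated correlation). Vegfa, which maintains the glomerular endothelium, fell by 2.10 (adjusted p = 5.03e-09), with falls also in Angptl2 (-3.01), Angpt2 (-3.07) and Sema3c (-1.54). Pdgfb (0.65) and Nrp2 (0.40) rose. The call of Pxn (adjusted p = 0.0346) was lost without any 1 of 7 libraries (adjusted p up to 0.0951) and that of Nrp2 (adjusted p = 0.041) without any 1 of 8 (adjusted p up to 0.168), and Nrp2 went to 0.03 with the proximal tubule covariate (adjusted p = 0.908).

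**Figure D3:**
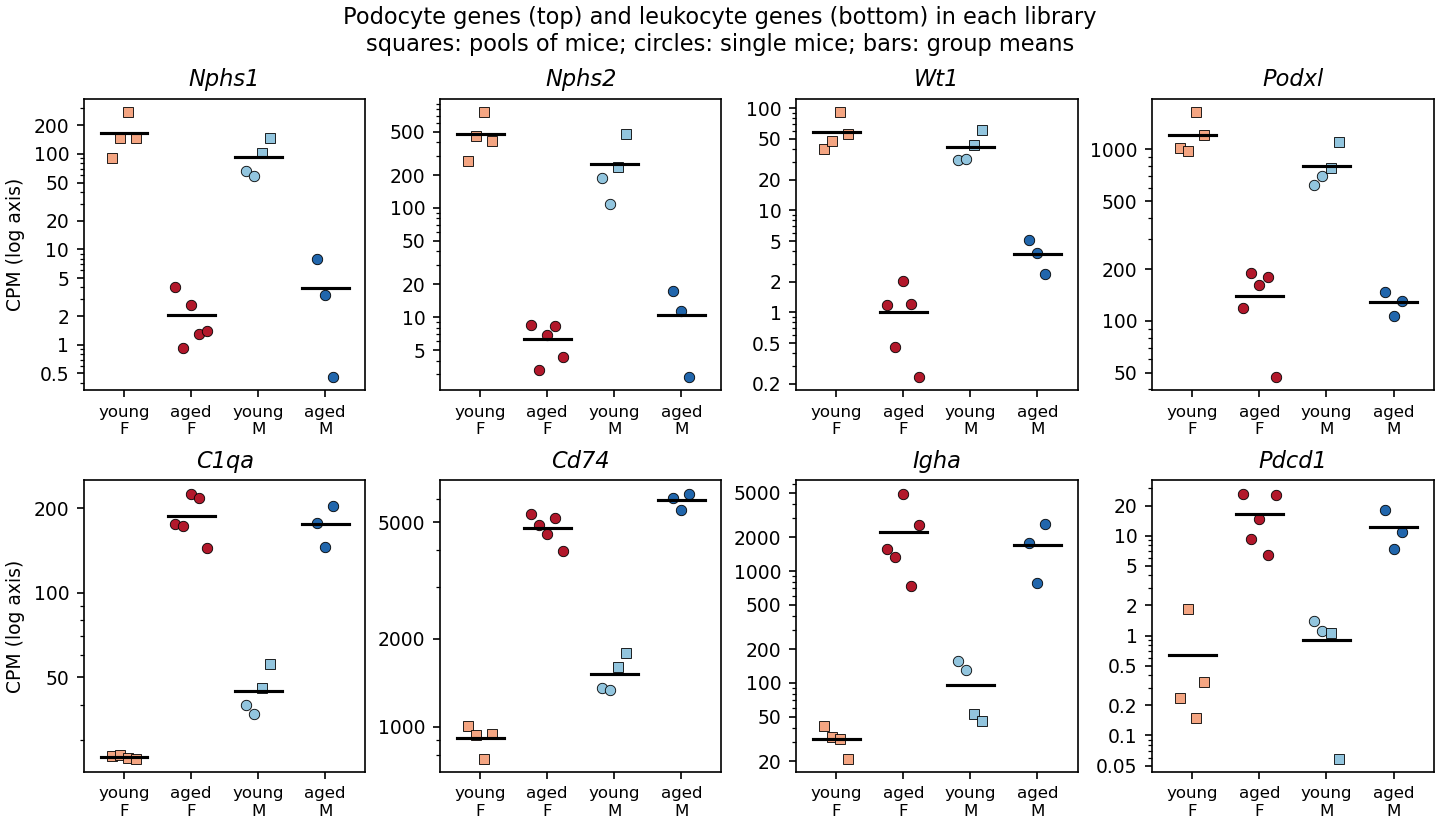
Normalised expression (CPM, log y axis) of 8 genes in each of the 16 libraries, with bars at the group means. Nphs1, Nphs2, Wt1 and Podxl were lower, and C1qa, Cd74, Igha and Pdcd1 higher, in aged than in young libraries.

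The 12 largest rises by the rule for named genes included genes of plasma cells and of macrophages. Cd5l, a secreted protein of macrophages (chromosome 3, 87357881 to 87371073, plus strand), rose by 8.61 (SE 1.24, adjusted p = 5.07e-05), with 1801 counts over the aged and 4 over the young libraries. Antibody constant genes clustered on chromosome 12 rose: Ighg3 (7.70), Ighg1 (7.19, adjusted p = 0.000112), Ighg2c (6.63), Ighg2b (6.62, adjusted p = 1.04e-05) and Igha (5.14, SE 0.44, adjusted p = 5.32e-08). Jchain, which joins antibody polymers, rose by 5.01, to 831 ± 494 CPM (SD, n = 8), and Mzb1, a plasma cell chaperone, by 4.78. Rises were also large in the lectin Fcna (6.03), the macrophage protease Adamdec1 (5.53), the protease inhibitor Slpi (5.40) and the inhibitory T cell receptor Tigit (4.24). All 8 aged libraries lay above all 8 young ones in these genes, again as the rule that picked them required. With a term for pooled libraries the calls were lost of Cd5l, whose change stayed at 8.61 (adjusted p = 1), and of Ighg3 (5.32, adjusted p = 1), Ighg2c (3.41, 0.297) and Slpi (3.93, 0.212), whose changes shrank, and that of Ighg3 also with limma voom (0.173) and the proximal tubule covariate (0.0726).

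Leukocyte markers rose as groups. All 20 macrophage and dendritic cell markers rose, with a median of 2.38 (adjusted p = 4.51e-27, and adjusted p = 0.0196 with an estimated correlation). C1qa, a complement subunit made by macrophages, rose by 2.41 (adjusted p = 6.51e-11), to 183 ± 30.4 CPM from 35.4 ± 11.3 CPM (SD, n = 8 each), as did C1qb (2.40), C1qc (2.36) and Aif1 (2.27). All 23 lymphocyte and plasma cell markers rose (median 2.90, adjusted p = 4.07e-14, and adjusted p = 0.0459 with an estimated correlation), among them Ighm (3.97), the T cell receptor subunit Cd3e (3.33), Cd37 (2.57) and Coro1a (2.51). All 7 MHC class II genes, which present peptides to helper T cells, rose at a median of 2.29 (adjusted p = 3.59e-20, and adjusted p = 0.0135 with an estimated correlation). Cd74, their invariant chain, reached 5212 ± 749 CPM from 1219 ± 357 CPM (SD, n = 8 each, 2.17), and H2-Eb1 (2.54), H2-Aa (2.40) and H2-Ab1 (2.31) rose too. MHC class I and antigen processing genes had 20 rises in 22, including Psmb8 (1.56), Psmb9 (1.52), H2-K1 (1.33) and H2-D1 (1.09), at a median of 1.00 (adjusted p = 8.44e-07, and adjusted p = 0.196 with an estimated correlation).

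Immune checkpoint genes rose in 16 of 19 cases and fell in 3 (median 1.99, adjusted p = 3.8e-07, and adjusted p = 0.0196 with an estimated correlation). Pdcd1 (PD-1, an inhibitory receptor of lymphocytes) rose by 4.20 (SE 0.51, adjusted p = 2.5e-06), to 14.8 ± 7.86 CPM from 0.775 ± 0.665 CPM, and its ligand Cd274 (PD-L1) by 1.46 (SE 0.17, adjusted p = 1.34e-06), to 54.4 ± 8.66 CPM from 19.4 ± 7.63 CPM (SD, n = 8 each). Havcr2 (2.65), Btla (2.59), Cd86 (2.22) and Vsir (2.20) rose, whereas Vtcn1 (-4.24), the adhesion ligand Nectin2 (-1.59) and Cd200 (-0.77) fell. In the NF-kB and inflammatory cytokine list 28 of 33 genes rose (median 1.67, adjusted p = 1.27e-15, and adjusted p = 0.0252 with an estimated correlation), among them the feedback inhibitors Tnfaip3 (2.67) and Nfkbie (2.00), Traf1 (2.27) and Nfkb2 (1.34), and the receptor gene Il1r1 fell (-1.09). The percent of counts in macrophage markers rose 5.88-fold alongside these lists.

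Cell cycle genes rose. All 22 proliferation genes rose at a median of 1.98 (adjusted p = 1.8e-10, and adjusted p = 0.0459 with an estimated correlation), with Mki67, a marker of cycling cells, at 245 ± 33.2 CPM (SD, n = 8) in aged libraries (2.38), Bub1b at 2.29, Top2a at 2.16 and Cenpa at 2.13. The percent of counts in macrophage markers (5.88-fold) and in lymphocyte and plasma cell markers (24.3-fold) rose alongside them. The senescence and cell cycle inhibitor list had 13 rises and 6 falls in 26 (median 0.72, adjusted p = 0.0205, and adjusted p = 0.251 with an estimated correlation), with the matrix proteases Mmp12 (3.32) and Mmp13 (2.39), the chemokine Cxcl2 (1.90) and Plaur (1.46) among the risers. Cdkn1a (p21, a cell cycle inhibitor) averaged 71.4 ± 11.2 CPM in aged and 58.6 ± 16.4 CPM in young libraries (SD, n = 8 each) and did not pass (0.25, adjusted p = 0.14), but did without young female 1 (adjusted p = 0.00538), with limma voom (0.0432) and with total count scaling (0.0249). Cdkn2a (p16) was too low to test, with 17 counts over the aged females, 7 over the aged males, 2 over the young females and 0 over the young males. Apoptosis and p53 target genes rose in 12 of 28 cases and fell in 4 (median 0.19, adjusted p = 0.0205, and adjusted p = 0.196 with an estimated correlation). Pmaip1 (2.30), Bcl2l11 (1.64), Apaf1 (1.57) and Bak1 (1.02), all promoters of cell death, rose. The survival gene Bcl2l1 (-0.67), Perp (-1.30), the death receptor Fas (-0.55) and the death promoter Bad (-0.41) fell. The call of Fas was lost without any 1 of 4 libraries (adjusted p up to 0.083) and that of Bad without any 1 of 6 (adjusted p up to 0.103), and Bad went to -0.24 with the proximal tubule covariate (adjusted p = 0.42).

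Metabolic genes moved in opposite directions. The percent of counts in macrophage (5.88-fold) and in lymphocyte and plasma cell markers (24.3-fold) rose alongside, and that in proximal tubule markers fell (2.18-fold). Whether the metabolic changes lay within podocytes was not tested. All 45 cytosolic ribosomal protein genes rose (median 1.00, adjusted p = 8.38e-24, and adjusted p = 0.0252 with an estimated correlation), for example Rplp0 (1.26), Rps19 (1.25), Rpl34 (1.18) and Rps28 (1.15). All 13 mitochondrially encoded genes fell (median -1.45, adjusted p = 0.000104, and adjusted p = 0.384 with an estimated correlation), including mt-Nd2 (-1.65), mt-Nd5 (-1.53), mt-Atp6 (-1.51) and mt-Cytb (-1.45). Nuclear-encoded oxidative phosphorylation genes fell in 33 of 36 cases (median -0.70, adjusted p = 2.03e-06, and adjusted p = 0.412 with an estimated correlation), with Ndufb8 (-1.24), Ndufa5 (-1.22), Cycs (-0.93) and Ndufs1 (-0.82) as examples. Lysosome and autophagy genes had 14 rises and 5 falls in 29 (median 0.22, adjusted p = 0.0011, and adjusted p = 0.196 with an estimated correlation). The lysosomal proteins Psap (1.78), Ctsb (1.76), Ctsz (1.58) and Npc2 (1.41) rose, whereas the protease Ctsl (-0.91), the autophagy genes Gabarapl1 (-1.56), Wipi1 (-0.59) and Ulk1 (-0.44), and Cd63 (-0.38) fell. Cd63 lost its call without any 1 of 9 libraries (adjusted p up to 0.108) and without the single-animal young males (0.166). With the proximal tubule covariate the calls of Ulk1 (adjusted p = 0.378), Wipi1 (0.311) and Cd63 (0.95) were lost, as they were with total count scaling (0.181, 0.0813 and 0.452). Cholesterol and lipid handling genes rose in 17 of 29 cases and fell in 6 (median 0.49, adjusted p = 0.00687, and adjusted p = 0.251 with an estimated correlation). Apoe, a lipid carrier, rose by 2.08, to 1718 ± 389 CPM from 390 ± 105 CPM (SD, n = 8 each), and the lipid droplet gene Plin2 (2.07), the exporter Abcg1 (1.77) and the cholesterol esterifier Soat1 (1.44) rose as well. Immediate early and dissociation response genes rose in 18 of 31 cases (median 0.54, adjusted p = 0.000583, and adjusted p = 0.445 with an estimated correlation), including Nr4a2 (1.96), Nr4a1 (1.79), Fosl2 (1.59) and Myc (1.51).

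Actin and signalling genes moved in both directions. Actin and Rho GTPase genes had 16 rises and 7 falls in 25 (median 0.47, adjusted p = 0.034, and adjusted p = 0.412 with an estimated correlation), with filamin Flna (1.58), profilin Pfn1 (1.35) and Actr3 (1.32) up and Enah (-1.95) down. That call was lost without aged female 2 (adjusted p = 0.0525), without young female 2 (0.0603), without the single-animal young males (0.116), with at least 50 counts in 3 libraries (0.051), with the proximal tubule covariate (0.0849) and with total count scaling (0.064). YAP and serum response factor targets had 11 falls and 4 rises in 16 (median -1.08, adjusted p = 0.0301, and adjusted p = 0.467 with an estimated correlation), and the call was lost without aged male 1 (adjusted p = 0.0545) and with at least 50 counts in 3 libraries (0.0525). Amotl2 (-2.13) and Tead1 (-2.00) fell, and the receptor kinase Axl (1.94), the actins Actb (1.40) and Actg1 (0.86), and Tagln2 (0.97) rose. The summed percent of counts of this list went the other way from its median, at 0.756 ± 0.0848% in aged and 0.379 ± 0.0813% in young libraries (SD, n = 8 each). Wnt genes fell in 17 of 24 cases (median -0.79, adjusted p = 0.000817, and adjusted p = 0.196 with an estimated correlation), for example Fzd2 (-3.16), Tcf7l1 (-1.80) and the coreceptor Lrp6 (-0.85), and the T cell factor Tcf7 rose (2.30). Markers of other kidney cells fell: 12 of 15 parietal (median -1.45, adjusted p = 9.96e-05), 24 of 28 proximal tubule (-1.30, 0.00149), 18 of 20 loop, distal and collecting duct (-1.36, 4.05e-06), 21 of 23 endothelial (-1.30, 2.05e-05), 14 of 18 mesangial and smooth muscle (-1.19, 0.000636) and 6 of 6 erythroid (-3.76, 0.0258). With an estimated correlation their adjusted p were 0.196, 0.523, 0.196, 0.412, 0.391 and 0.412, and the erythroid call was also lost with additive age and sex (0.0733), age alone (0.0607) and the proximal tubule covariate (0.0822). The covariate also ended the proximal tubule call, which it contains (median -0.20, adjusted p = 0.226), and the calls of Gatm (0.212), Hba-a1 (0.0557), Hbb-bs (0.0697) and Alas2 (0.0512). Examples were Pax8 (-2.12), Pax2 (-2.22) and Krt18 (-2.16), Slc5a12 (-1.87), Acsm2 (-1.45), Aqp1 (-1.38) and Gatm (-1.30), Slc4a1 (-2.39), Scnn1g (-1.94), Atp6v0d2 (-1.72) and Krt7 (-1.48), Ehd3 (-2.74), Kdr (-2.05), Cldn5 (-1.71) and Egfl7 (-1.35), Myh11 (-2.30), Mylk (-1.92), Des (-1.54) and Notch3 (-1.38), and Hba-a1 (-3.92), Hbb-bs (-3.81) and Alas2 (-3.77). Cd44 (2.29), an adhesion receptor of activated parietal cells and of leukocytes, and the tight junction gene Cldn1 (1.15) rose.

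The remaining 8 lists did not pass. Interferon response genes had 16 rises and 7 falls in 36 (median 0.27, adjusted p = 0.212), with Irf8 (2.01), Ifi27l2a (1.74) and Zbp1 (1.54) up and Ifit3 (-2.18) down, but passed without young female 1 (adjusted p = 0.0326). Complement genes had 5 rises and 3 falls in 16 (0.08, 0.398), with the receptors C5ar1 (2.13) and C3ar1 (1.99) and properdin Cfp (3.19) up and the protective Cd59a (-2.29), Cfb (-0.63) and Clu (-0.32) down. Cfb lost its call without any 1 of 12 libraries (adjusted p up to 0.138) and Clu without any 1 of 11 (adjusted p up to 0.0978). Extracellular matrix and TGF-beta genes had 10 rises and 6 falls in 33 (0.08, 0.28), with Tgfbi (2.26), Fn1 (1.89), Tgfb1 (1.87) and Tgfbr1 (1.56) up, but passed with the term for pooled libraries (median 0.56, adjusted p = 0.0261). Notch genes had 4 rises and 9 falls in 16 (-0.70, 0.67). Lfng (2.02), Notch2 (1.29), Rbpj (1.20) and Mfng (0.74) were the risers, and the target gene Hey2 (-2.45) fell. The unfolded protein response had 8 rises and 1 fall in 21 (0.18, 0.263): Sdf2l1 (1.38), Ern1 (0.89), Atf6 (0.77) and Xbp1 (0.58) rose, and the chaperone Dnajb9 (-0.40) fell. This list too passed with the term for pooled libraries (median 0.49, adjusted p = 0.0321). Oxidative stress genes had 6 rises and 11 falls in 25 (-0.24, 0.672), with Hmox1 (1.92), Ucp2 (1.64), Nfe2l2 (0.98) and Gsr (0.94) up. Clock genes had 5 rises and 12 falls in 19 (-0.51, 0.28), with Npas2 (-2.21) and Nr1d1 (-1.67) down and Nfil3 (1.72), Per1 (1.30), Ciart (1.10), Cry1 (0.68) and Bhlhe40 (0.50) up. Y-linked and X-inactivation genes had 5 rises in 10 (0.17, 0.67), among them Xist (1.31, adjusted p = 0.00737), Kdm5d (1.52, adjusted p = 0.00292), Kdm6a (0.32) and Kdm5c (0.24). The Xist value rests in males on 11 counts over the aged and 3 over the young libraries, and its call was lost with age alone (adjusted p = 0.647), limma voom (0.0886) and the term for pooled libraries (0.363). The Kdm5d value rests on 16 counts over the aged and 2 over the young females, and its call was lost with additive age and sex (adjusted p = 0.171) and age alone (0.921). Ddx3y did not pass (-0.53, adjusted p = 0.365) and changed sign without young female 1 (0.19).

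Counts adjusted over the list alone equalled those over all genes except for slit diaphragm (25 falls), VEGF (13 falls), senescence (15 rises), NF-kB (29 rises), complement (1 fall), clock (13 falls) and proximal tubule genes (2 rises).

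**Figure D4:**
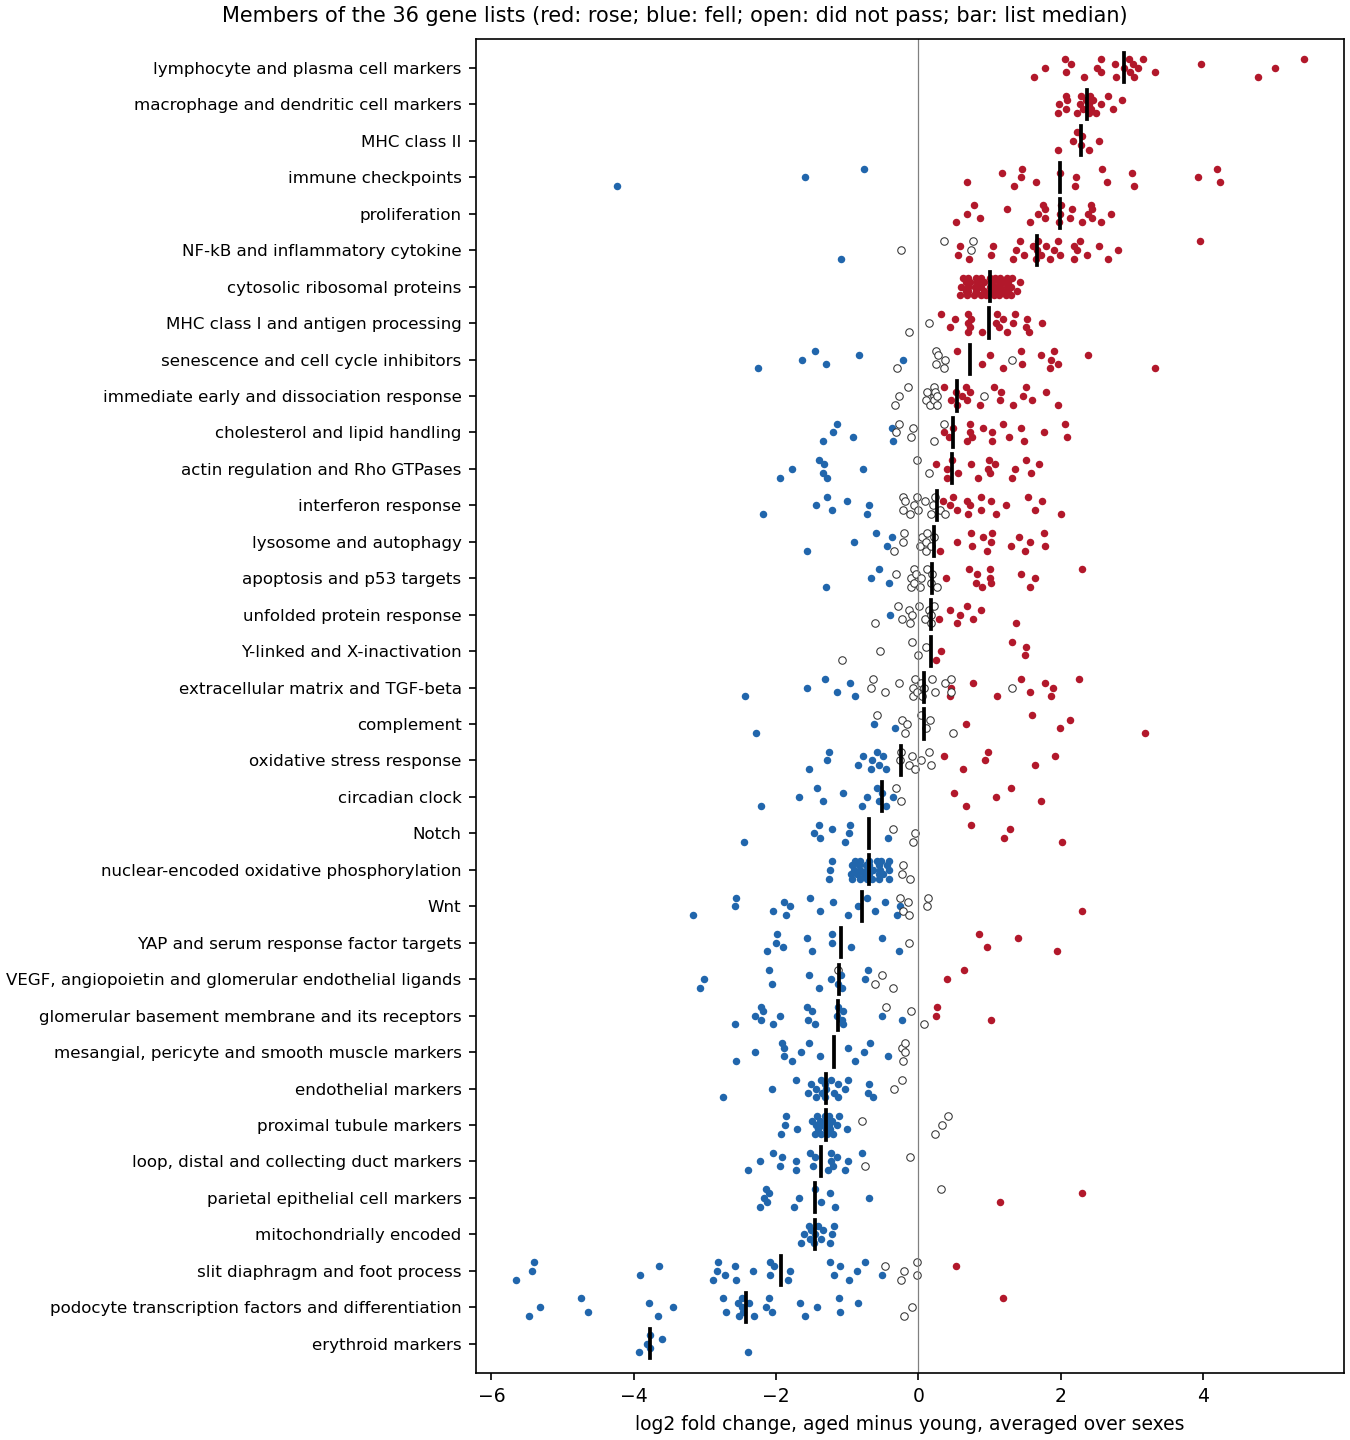
Log2 fold changes, aged over young averaged over the sexes, of the members of 36 gene lists (x axis), with 1 list per line, a bar at each list's median, red for members that rose, blue for members that fell and open points for members that did not pass. The median was highest for lymphocyte and plasma cell markers (2.90) and lowest for erythroid markers (-3.76).

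Of the choices in the fit, a term for pooled libraries, which young males alone inform, lowered the count to 6873 genes (3316 up and 3557 down), and 32 of 202 gene results lost the call or changed sign under at least 1 alternative. Besides the losses given above, the pool term ended the calls of Bad, Bcl2l1, Bhlhe40, Cd200, Cfb, Ciart, Clu, Ctsl, Dnajb9, Fas, Ilk, Kdm5c, Kdm6a, Mfng, Nrp2, Pdgfb, Pxn, Wipi1 and Xbp1 (adjusted p 0.0519 to 0.932). With this term the changes of Cd200 (-0.9987), Clu (-0.48), Fas (-0.64), Ilk (0.29), Kdm5c (0.31) and Wipi1 (-0.79) were larger in size than in the main test. The changes of the other genes named shrank, for example to -0.04 for Bad, 0.11 for Kdm6a and 0.54 for Xbp1. The proximal tubule covariate ended the calls of Cfb (adjusted p = 0.673), Clu (0.235), Ilk (0.0568), Kdm5c (0.114) and Kdm6a (0.157). Total count scaling, in which the median of all genes lay at 0.22 on the log2 scale averaged over the sexes, at 0.39 in males and at -0.28 between the sexes in young mice, gave 7023 rises and 3865 falls.

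Whether the changes with age held within each sex was asked next. In females podocyte genes fell, and antibody and macrophage genes rose. Nphs1 averaged 2.05 ± 1.28 CPM in aged (SD, n = 5) and 164 ± 77.5 CPM in young females (SD, n = 4), and fell by 6.30 (SE 0.59, adjusted p = 2.64e-07). Lmx1b (-6.66), Nphs2 (-6.22), the sarcomere gene Myom2 (-5.82) and Wt1 (-5.81) made up the other largest falls. The largest rises were in Ighg1 (8.67, adjusted p = 0.000788), Ighg2b (8.62), Cd5l (8.50), Ighg3 (8.49) and Ighg2c (7.59). With limma voom the calls of Ighg1 (adjusted p = 0.102), Cd5l (0.149), Ighg3 (0.276) and Ighg2c (0.0559) were lost, as were those of Cd5l (1), Ighg3 (0.991) and Ighg2c (0.693) with the term for pooled libraries. The change of Cd5l was still 7.29 with limma voom and 8.50 with that term. In total 9584 genes changed (4880 up and 4704 down).

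Slit diaphragm genes fell in 26 of 30 cases (median -2.18, adjusted p = 8.85e-16, and adjusted p = 0.0728 with an estimated correlation) and podocyte transcription factor genes in 24 of 28 (median -2.61, adjusted p = 4.56e-17, and adjusted p = 0.0728 with an estimated correlation). All 20 macrophage markers rose (median 2.75, adjusted p = 1.89e-28, and adjusted p = 0.015 with an estimated correlation), as did all 23 lymphocyte and plasma cell markers (median 3.44, adjusted p = 4.91e-15, and adjusted p = 0.0404 with an estimated correlation) and all 7 MHC class II genes (median 2.52, adjusted p = 1.33e-19, and adjusted p = 0.013 with an estimated correlation). Proliferation genes rose in 20 of 22 cases (adjusted p = 2.03e-10, and adjusted p = 0.0374 with an estimated correlation) and immune checkpoints in 16 of 19 (adjusted p = 4e-07, and adjusted p = 0.015 with an estimated correlation). Mitochondrially encoded genes fell in 7 of 13 cases (median -0.73, adjusted p = 0.0453, and adjusted p = 0.644 with an estimated correlation). Adjusted over the list alone these counts were the same except for 25 podocyte transcription factor genes and 9 mitochondrial genes. The percent of counts in macrophage markers was 6.71-fold and in lymphocyte and plasma cell markers 35.4-fold higher, and in slit diaphragm genes 3.16-fold lower (exact p = 0.00794 and adjusted p = 0.0113 each). Endothelial (2.31-fold) and loop and duct markers (1.69-fold) were lower (exact p = 0.0159 and adjusted p = 0.0159 each), but the endothelial result was lost without young female 1 (adjusted p = 0.0714) or 4 (0.0536), and the loop and duct result without young female 3 (0.0536).

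All young female libraries were pools and all aged female libraries single mice, so pooling and age cannot be separated within females. The mitochondrial list lost its call without aged female 1 (adjusted p = 0.0679), 4 (0.0613) or 5 (0.0644), aged male 1 (0.0505), or young female 2 (0.0679) or 3 (0.112), with at least 50 counts in 3 libraries (0.0758), and with the proximal tubule covariate (median -0.40, adjusted p = 0.212), while its median was -1.85 with the term for pooled libraries (adjusted p = 1.19e-07), and the count of genes was 6049 with this covariate and 4994 with this term.

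In males podocyte genes fell, and antibody and macrophage genes rose. Nphs1 averaged 3.92 ± 3.81 CPM in aged (SD, n = 3) and 93.5 ± 40.0 CPM in young males (SD, n = 4). Hemoglobin genes, which red cell precursors express, had the largest falls: Hba-a1 (-6.54, SE 1.33, adjusted p = 0.00133), Hbb-bs (-6.52), Hba-a2 (-6.19) and Hbb-bt (-6.18), followed by the heme synthesis gene Alas2 (-5.72). The size of these falls depends on the single-animal young males 1 and 2, with 0.126% and 0.21% of counts in erythroid markers. The pooled young males 3 and 4 had 0.0162% and 0.0202%, and aged males 0.00133 to 0.00495%. Adamdec1 (5.94, adjusted p = 1.99e-05), Ighg1 (5.72) and Ighg2c (5.67) rose. Cd5l rose at least 67.9-fold (adjusted p = 0.00751), with 167 counts in aged and 0 in young males, against a floor of 3 counts over the group. Ighg3 was higher by a ratio of 145 (95% counting interval 39.6 to 1200), from 2 counts in young males (adjusted p = 0.0165), and lost its call without aged male 3 (adjusted p = 0.414), without pooled young males (0.121), without the single-animal young males (0.0754), with limma voom (0.471), with the proximal tubule covariate (0.353) and with the term for pooled libraries (0.129). The call of Cd5l was lost with limma voom (adjusted p = 0.154), with the term for pooled libraries (0.0509) and without pooled young males (0.0527), and that of Ighg1 with limma voom (0.128) and without the single-animal young males (0.0799). In total 7556 genes changed, 3852 up and 3704 down.

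Slit diaphragm genes fell in 21 of 30 cases (median -1.52, adjusted p = 1.51e-10, and adjusted p = 0.177 with an estimated correlation) and podocyte transcription factor genes in 24 of 28 (median -2.03, adjusted p = 1.48e-12, and adjusted p = 0.157 with an estimated correlation). All 20 macrophage markers (median 1.97, adjusted p = 9.82e-23, and adjusted p = 0.0352 with an estimated correlation) and all 7 MHC class II genes (median 2.07, adjusted p = 1.47e-18, and adjusted p = 0.0156 with an estimated correlation) rose. All 23 lymphocyte and plasma cell markers rose (median 2.30, adjusted p = 2.26e-11, and adjusted p = 0.0654 with an estimated correlation). Proliferation genes rose in 21 of 22 cases (adjusted p = 1.63e-09, and adjusted p = 0.0441 with an estimated correlation) and immune checkpoints in 15 of 19 (adjusted p = 1.75e-06, and adjusted p = 0.0352 with an estimated correlation). Mitochondrially encoded genes fell in 13 of 13 cases (median -2.15, adjusted p = 1.74e-08, and adjusted p = 0.236 with an estimated correlation), beside a 2.42-fold lower percent of mitochondrial ribosomal RNA (exact p = 0.0286, the smallest possible with 3 against 4). Adjusted over the list alone these counts were the same except for 22 slit diaphragm and 25 transcription factor genes that fell and 16 checkpoint genes that rose. The percent of counts in macrophage markers was 5.10-fold and in lymphocyte and plasma cell markers 15.6-fold higher, and in erythroid markers 19.4-fold lower, without passing after adjustment (adjusted p = 0.0714 each, exact permutation). Slit diaphragm genes (1.75-fold lower) and podocyte transcription factor genes (2.04-fold lower) did not pass by this measure either (exact p = 0.0571 and adjusted p = 0.0816 each), nor did proximal tubule (exact p = 0.2) and parietal markers (exact p = 0.286). The macrophage, lymphocyte, erythroid, slit diaphragm and podocyte transcription factor lists all passed with the total without mitochondrial genes (adjusted p = 0.0317 each) and with the mean log2 CPM of the members (0.0476 each), and the parietal list with the former alone (0.0317). Of the genes changed in both sexes, 3466 rose in both against 1063 expected if the sexes were independent, 3096 fell in both against 985.2, and 10 moved oppositely. The correlation of the male with the female log2 change was 0.858 across genes, which are not independent replicates. Young males 1 and 2 were single animals, and without them 6628 genes changed, while total count scaling gave 6285 rises and 1863 falls.

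The difference between the male and the female age change tested whether aging differed by sex. In 5 genes the change in males was lower than in females, and none was higher, by edgeR, while 1334 genes had an unadjusted p under 0.05. All 5 encode small noncoding RNAs or are predicted genes, and 4 of them were chosen after their values were seen. n-R5s156, a 5S ribosomal RNA (chromosome 7, 99497718 to 99497822, plus strand), had a difference of -3.30 (SE 0.52, adjusted p = 0.0322), with 16.7 ± 7.25 CPM in young (SD, n = 4) and 1.91 ± 0.506 CPM in aged males (SD, n = 3). Young females averaged 3.67 ± 1.71 CPM (SD, n = 4) and aged females 4.13 ± 1.07 CPM (SD, n = 5). The mitochondrial transfer RNA mt-Tk (-5.06, adjusted p = 0.0322), n-R5s56 (-3.38, adjusted p = 0.00255), Gm23935 (-3.43, adjusted p = 0.0322) and Gm25099 (-2.22, adjusted p = 0.0457) likewise fell in males and did not pass in females (adjusted p 0.0798 to 0.689).

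As groups, erythroid markers (median -5.00, adjusted p = 3.62e-06, and adjusted p = 0.212 with an estimated correlation) and mitochondrially encoded genes (-1.43, adjusted p = 2.7e-16, and adjusted p = 0.127 with an estimated correlation) fell further in males. Erythroid markers were highest in the single-animal young males 1 and 2 (0.126% and 0.21% of counts). The pooled young males 3 and 4 (0.0162% and 0.0202%) lay in the range of young females (0.00832 to 0.0237%). Macrophage markers (-0.72, adjusted p = 2.7e-16, and adjusted p = 0.127 with an estimated correlation) and lymphocyte and plasma cell markers (-1.13, adjusted p = 9.27e-13, and adjusted p = 0.127 with an estimated correlation) had a smaller rise in males. No member of the 36 lists passed over all genes, and adjusted over the list alone 13 mitochondrial, 9 macrophage and 7 lymphocyte genes had a lower change in males. With an estimated correlation none of the 36 lists passed. The median, mean and test differed in sign for complement (0.20, -0.04 and down), Y-linked and X-inactivation (0.10, -0.57 and down), actin (-0.03, 0.01 and up) and matrix genes (-0.03, 0.003 and up), none of which passed.

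The count of 5 ranged from 1 to 58 when 1 library was left out: it was 58 without young female 4, 11 without young female 3, 8 without aged female 1 or young male 1, 6 without aged female 5, 4 without aged female 3, 2 without aged female 4 or young male 3, and 1 without each of the other 8, and n-R5s56 was called each time. The other 4 genes lost their calls with the proximal tubule covariate (adjusted p 0.0528 to 0.0544) and with total count scaling (0.0617 to 0.194). DESeq2 gave 152 and limma voom 55.

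In young mice, the largest differences between male and female libraries included Xist and genes of chromosome Y. Xist, the RNA that silences an X chromosome in females (chromosome X, 103460366 to 103483254, minus strand), was higher in females by a ratio of 17500 (95% counting interval 5980 to 84800). Males were higher at least 723-fold in Uty and at least 562-fold in Eif2s3y, and by a ratio of 5190 (930 to 205000) in Ddx3y and 1000 (277 to 8280) in Kdm5d, all on chromosome Y. The protease inhibitor Pzp (at least 500-fold) was higher in males. Ugt1a2, a detoxifying enzyme (-7.48), the fatty acid hydroxylase Cyp4a14 (-6.88), the amino acid transporter Slc7a12 (-5.40) and the prolactin receptor Prlr (-4.68) were lower in males, with Ugt1a2 at 0.339 ± 0.288 CPM in males against 71.3 ± 46.3 CPM in females (SD, n = 4 each). In total 378 genes differed, 321 higher and 57 lower in males. All 7 MHC class II genes were higher in males (median 0.94, adjusted over the list alone also 7), as were 5 of 28 proximal tubule markers (6 adjusted over the list alone).

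Young males included the 2 single-animal libraries with the most mitochondrial RNA, and without both 166 genes differed. The count was 206 without young male 1, 213 without young male 2 and 227 without young female 1, and it was 217 with a term for pooled libraries, 748 with DESeq2 and 848 with limma voom, while total count scaling gave 126 higher and 188 lower.

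In aged mice males and females differed in 51 genes, 40 higher and 11 lower in males. Ddx3y was at least 2030-fold and Eif2s3y at least 614-fold higher in males, and Uty by 8.74 on the log2 scale. The organic anion transporter Slco1a1 was higher by a ratio of 1540 (95% counting interval 276 to 61000) and the amino acid transporter Slc7a13 by 1100 (304 to 9100), both genes of proximal tubules. Xist (-12.51), Cyp4a14 (-4.72, adjusted p = 0.00282), Ugt1a2 (-4.47), Slc7a12 (-3.49, adjusted p = 0.047) and Prlr (-2.76, adjusted p = 0.0106) were lower in males. Of the genes called at both ages, 32 were higher in males, against 0.726 expected if independent, and 9 lower, against 0.0355. Proximal tubule markers were higher in males in 6 of 28 cases (7 adjusted over the list alone). Aged male 1 had 0.910% of counts in these markers, against 0.357% and 0.252% in aged males 2 and 3.

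Slc7a12 lost its call without any 1 of 12 libraries (adjusted p up to 0.315), with limma voom (0.0683), no filter (0.172) and the term for pooled libraries (0.0782), and without pooled (0.0646) or single-animal young males (0.0816), Prlr without aged male 2 (adjusted p = 0.0724) and Cyp4a14 with limma voom (adjusted p = 0.185). The count was 33 without aged male 1, 30 with only these groups in the fit, 86 with DESeq2 and 136 with the proximal tubule covariate.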

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

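Chosen after the result was seen were the tests of the macrophage to endothelial ratio, of the Nphs1 to Nphs2 ratio, and of the mitochondrial fall in females, without TMM scaling, with the tubule covariate and without the single-animal young males.

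Podocyte transcripts were lower and leukocyte transcripts higher in every aged library. A lower share of podocytes alone would raise the markers of all other cells alike, and lower expression within podocytes alone, in an unchanged mix of cells, would leave the ratio between other cell types as it was. Yet the log2 ratio of macrophage to endothelial counts rose by 3.554, from -1.183 ± 0.654 to 2.37 ± 0.520 (SD, n = 8 each, exact p = 0.000155, the smallest possible). This ratio restates the macrophage rise and the endothelial fall already seen, so its p is no separate support. The opposite directions of those lists argue against both explanations. Leukocytes among the sorted cells are a candidate explanation, although sorting for tdTomato should remove them: of 20 leukocyte genes outside the fixed lists 19 were tested and 19 rose 2-fold or more (median 2.265, p = 4.41e-26, and p = 0.00279 with an estimated correlation), with Lcp1 at 861 ± 131 CPM and Cybb at 572 ± 86.5 CPM (SD) in aged libraries, and all 19 averaged at least 1 CPM in young libraries. Lower expression within the remaining podocytes stays open besides, since the log2 ratio of Nphs1 to Nphs2 changed by -0.3445 (exact p = 0.183, n = 8 each), and a change of age in the kidney, the biology the design names, was not tested apart from the cell mix.

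Mitochondrially encoded transcripts were lower in aged libraries. The single-animal young males are not the whole cause, since the averaged median without them was -1.20 (adjusted p = 8.4e-05) and the log2 percent of counts also changed in females, by -0.6971 (exact p = 0.0397, adjusted p = 0.0476, n = 5 and 4). TMM scaling is argued against as the cause, because the log2 percent of total counts, which does not use it, changed by -1.104 over all libraries (exact p = 0.000466, n = 8 each). Such a percent still depends on the other RNA in a library, so dilution by RNA of other cells was not excluded. RNA of proximal tubule cells, which are rich in mitochondria, was not excluded as a cause. Averaged over the sexes, the proximal tubule covariate moved the median from -1.451 (median SE of the genes 0.228) to -1.159 (SE 0.335, adjusted p = 0.00114). In males the median with the covariate was -1.904 (SE 0.402). The covariate itself differs with age and may capture tubule RNA only in part, so a remaining fall cannot decide the question. In females the covariate moved the median from -0.7262 (SE 0.293) to -0.3994 (SE 0.409) and the call ended (adjusted p = 0.212), with a smaller change and a wider error, so that tubule RNA and age cannot be told apart there. Markers of loop, distal and collecting duct, also 2.05-fold lower in aged libraries, were not used as a covariate. Among young libraries their percent and that of mitochondrial messenger RNA were lowest in young female 1 (0.302% and 3.65%). Both were highest in young male 1 (0.631% and 9.43%), so RNA of those cells was not tested as a cause. Tubule RNA as a part of the fall stays open too, since within ages the percents of mitochondrial messenger RNA and of tubule markers gave r = 0.186 in young (permutation p = 0.668, rho 0.429, p = 0.299) and r = 0.214 in aged libraries (permutation p = 0.542, rho 0.333, p = 0.428; 8 libraries each, adjusted p = 0.668 for both r), or 0.568 and 0.244 without the 2 libraries farthest from the median, and a biological change with age was not tested.

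The fall of mitochondrially encoded transcripts was larger in males, with a median difference of -1.43 between the sexes (adjusted p = 2.7e-16, but 0.127 with an estimated correlation). Without the single-animal young males the median was -0.6889 (adjusted p = 3.62e-07), and without the pooled young males -1.85. The difference shrank and still passed at the preset correlation, so those libraries and a difference between the sexes cannot be told apart, because among the young libraries males alone include single animals.

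The age change differed between the sexes, by a test of the difference, in mt-Tk (-5.06), n-R5s56 (-3.38), n-R5s156 (-3.30), Gm23935 (-3.43) and Gm25099 (-2.22). At the preset correlation it also differed in 20 lists, given here by their median difference, male minus female, but with an estimated correlation none of the 36 lists passed. Positive medians were those of slit diaphragm (0.49), podocyte transcription factor (0.48), basement membrane (0.37), YAP (0.33), ribosomal protein (0.13), clock (0.35), immediate early (0.29), parietal (0.48), proximal tubule (0.53) and mesangial genes (0.65). That of proximal tubule genes went to -0.18 without aged male 1 and no longer passed (camera, adjusted p = 0.117). Negative medians were those of proliferation (-0.44), NF-kB (-0.17), MHC class II (-0.49), checkpoint (-0.45), oxidative phosphorylation (-0.22), mitochondrially encoded (-1.43), loop and duct (-0.72), macrophage (-0.72), lymphocyte and plasma cell (-1.13) and erythroid genes (-5.00). The percent of counts in erythroid markers was far higher in young males 1 and 2, the single animals, than in every other library.

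A library lay far from the others of its group in 18 of 138 groups of values, where chance gives about 1 in 20 if values are normally distributed. The values were not log-transformed, so that rate need not hold. Only groups of at least 4 libraries were checked, so the 3 aged male libraries were not. Among these, aged male 1 had 0.910% of counts in proximal tubule markers, against 0.357% and 0.252% in aged males 2 and 3. Aged female 3 had 3142 CPM of Ighg1 (others 106 to 277), 1766 CPM of Ighg2b (162 to 374) and 398 CPM of Slpi (10.6 to 24.9). Aged female 4 had 97.0 CPM of Cd5l (1.74 to 18.4), aged female 2 had 21.0% mitochondrial ribosomal RNA (12.6 to 14.8) and aged female 5 had 0.0787% of counts in parietal markers (0.108 to 0.119). Young female 1 had 8.61 CPM of Ighg2c (0.115 to 0.224), 0.703 CPM of Tigit (0.0572 to 0.0850) and 0.0586 CPM of Ddx3y (all others 0). Young female 2 had 1.83 CPM of Pdcd1 (0.150 to 0.340). Young female 3 had 7.41 CPM of Ighg1 (0 to 0.286), 329 CPM of Cdkn1c (129 to 144) and 0.0237% of counts in erythroid markers (0.00832 to 0.0101). Young male 1 had 23.8 CPM of Ighg2c (0.0587 to 1.34) and 0.2 CPM of Ighg3 (all others 0). Young male 3 had 5.47 CPM of Ighg1 (0 to 0.822). Young male 4 had 39.1 CPM of Lmx1b (9.6 to 14.6) and 22.6 CPM of Nell2 (8.74 to 10.4). Where all others were 0, which rests on 1 count of Ddx3y and 2 of Ighg3, any count would stand apart, so these 2 groups say nothing beside the rate expected by chance.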

How the results depend on the processing

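Total count scaling and leaving out the mitochondrial genes or the single-animal young males were tests chosen after seeing the data.

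With RLE size factors and upper quartile scaling all 144 list results kept their direction and call. Of 247 gene results, 46 lost the call or changed sign under at least 1 alternative, in 229 of 7353 values, and 3 calls were gained. The term for pooled libraries ended 30 gene calls, the proximal tubule covariate 18 and, with a change of sign, 2 more (Cd63 and Cfb), limma voom 13, leaving out the single-animal young males 13, total count scaling 12, and leaving out 1 library ended a call in 113 values. Among the 144 list results an estimated correlation ended 81 calls, and fry ended 21 and added 13. The cause was not tested for any value below unless it is stated.

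In males the count of changed genes stayed within 1.5 times of 7556, from 5863 to 10008, under all alternatives run. Other counts moved by over 1.5 times as follows. Averaged over the sexes 11142 became 6873 with the term for pooled libraries. In females 9584 became 6049 with the proximal tubule covariate and 4994 with the term for pooled libraries. For the difference between the sexes 5 became 13 with at least 50 counts in 3 libraries, where fewer genes were tested, 152 with DESeq2, 55 with limma voom, 17 with no filter, 2 with the proximal tubule covariate, 19 with the term for pooled libraries, 1 with total count scaling, 3 without mitochondrial genes, 29 without pooled young males and 8 without the single-animal young males. Between the sexes in young mice 378 became 748 with DESeq2, 848 with limma voom, 217 with the term for pooled libraries and 166 without the single-animal young males. In aged mice 51 became 86 with DESeq2, 30 with only the groups compared and 136 with the proximal tubule covariate. Leaving out 1 library gave 10354 to 11040 genes averaged over the sexes, 8578 to 9905 in females, 5863 to 7683 in males, 1 to 58 for the difference, 206 to 514 in young mice (206 without young male 1, 213 without young male 2, 227 without young female 1) and 33 to 58 in aged mice (33 without aged male 1).

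A sign changed in 66 values of 21 results, of which 59 passed in neither analysis. Genes in the averaged age comparison were Cd63 with the proximal tubule covariate (0.0153), Cfb with it (0.128), Kdm5d with age alone (-0.169), and Ddx3y with additive age and sex (0.355, adjusted p = 0.0386), DESeq2 (0.0547), limma voom (0.211) and 1 library left out (-0.689 to 0.186, above 0 without young female 1).

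List medians are given where the direction of the test reversed. With the proximal tubule covariate these were clock genes in males (0.179), interferon genes in females (-0.0736), MHC class I genes for the difference between the sexes (0.00170), oxidative stress genes averaged (-0.0157), in females (0.0728) and in males (-0.121), and proximal tubule markers for the difference (-0.344, adjusted p = 3.18e-05), which the covariate itself contains. The other reversals, save those of oxidative stress genes in females, were in the difference between the sexes. With the term for pooled libraries these were actin (-0.0895), matrix (-0.109) and oxidative stress genes (0.0412). Without the single-animal young males they were actin (-0.0695), matrix (-0.0912), interferon (0.00423) and oxidative stress genes (0.0588). Without pooled young males they were MHC class I (0.0797), senescence (0.0753) and unfolded protein response genes (-0.0119). With total count scaling they were lysosome (0.204), MHC class I (0.298), oxidative stress (0.255) and unfolded protein response genes (0.225). With at least 50 counts in 3 libraries they were apoptosis (-0.0245) and Y-linked and X-inactivation genes (0.104). With fry they were apoptosis genes (0.0190) and, in females, oxidative stress genes (-0.211).

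With 1 library left out, the medians of the difference ranged from -0.0538 to 0.0376 for actin, -0.0489 to 0.113 for apoptosis, -0.146 to 0.189 for endothelial, -0.199 to 0.169 for matrix, -0.210 to 0.214 for interferon (adjusted p = 0.0194 without young female 1), -0.226 to 0.0260 for MHC class I, -0.190 to 0.0455 for oxidative stress, -0.177 to 0.923 for proximal tubule, -0.185 to 0.115 for senescence, -0.189 to -0.0531 for unfolded protein response and 0.0572 to 0.165 for Y-linked and X-inactivation genes. Oxidative stress genes in females ranged from -0.320 to -0.147.

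Depth limited the tests of rare transcripts: Cdkn2a had 17 counts over the aged and 2 over the young females. No paired analysis was possible because the replicate numbers follow the order of the records.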

Other observations

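No test in this part was chosen after its result was seen.

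Regrouping of the libraries tested how often other splits gave as many changed genes. For the averaged age comparison 1 of 100 splits, the real one with 11142 genes, reached that count, and the highest other gave 8204. That split exchanged the age of every library except aged female 2 and young male 1, which makes it close to the mirror of the real one. In females it was 1 of 100 splits (9584 genes, highest other 7200) and in males 1 of 35 (7556 genes, highest other 3167). No other split tried reached any of the 3 counts, and 1 of 35 is the smallest share possible in males. Pooling and the cell mix differ between the same age groups, so the splits cannot separate them from age. Between the sexes the real split alone reached its count, as 1 of 35 splits in young mice (378 genes, highest other 1) and 1 of 56 in aged mice (51 genes, highest other 4). These too are the smallest shares possible. For the difference between the sexes in age change, 2 of 100 splits reached 5 genes, and the highest other gave 23. These splits exchanged sex within each age, so sex differences of the mice could enter them. Chance can therefore not be excluded from their share. The split with 23 genes exchanged the sex of all young libraries, of aged females 3 and 5 and of aged males 1 and 3, so it reversed the sexes in young mice and mixed them in aged mice. Its count lies above the real one. The sex differences of young mice, found in 378 genes, can enter such a split as a difference in age change. Other structure of the samples was not tested with splits.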
